A study of Caenorhabditis elegans with 6 samples.

How the data were processed

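RNA abundance was measured in whole, unfed first-stage (L1) larvae of the nematode Caenorhabditis elegans on 6 Affymetrix C. elegans arrays, 2 for each of 3 groups. The groups were elo-5(gk208) mutants raised by mothers given the fatty acid C13ISO, elo-5(gk208) mutants raised by mothers given C17ISO, and the wild-type strain N2 given C13ISO. Per the labels' protocols, every line first spent 1 generation on bacteria carrying 1 mM C17ISO, and the next generation received 1 mM of either C13ISO or C17ISO at 20 °C. Eggs from those adults were released by bleaching and left on plates without food for 24 h, after which the hatched larvae were collected and total RNA was extracted. The labels call the elo-5 C13ISO larvae C17ISO deficient, and the series design describes the arrays of a group as biological replicates.

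The deposited table holds 1 intensity per probe set and array on a linear scale, which the authors computed with the model-based method of the dChip program, per the labels. The dChip version, the use of mismatch probes and the normalization between arrays are not given in the sources used here. The linear scale was read from the values, which ran from 0.73 to 28838, the highest being a probe set bright on a single array whose reliability was not tested, with array medians of 107 to 134. The share of values below 16 was 18.3% to 20.9% per array. Array number, not sequencing depth, limits the precision here, with 2 arrays per group.

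The table lists 22548 probe sets, none of them array controls. Of these, 20766 carried 1 gene name in the platform annotation, 887 carried several and 895 carried none. Names were checked through Entrez IDs against a WBcel235 gene table, which held 20701 of the one-gene probe sets and was used only for names and for which genes neighbour each other. The named probe sets covered 17118 genes, 2981 of them with more than 1 probe set. Probe sets with several genes were tested but never named. In gene lists and families a gene stands for its brightest probe set. Counts of genes higher or lower include a gene if any of its one-gene probe sets was called, so a gene can be among both.

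Values were transformed as log2(value + 16), with the deposited normalization kept. Probe sets whose mean lay above the 30th percentile were tested, which left 15783. All 6 arrays entered a single limma fit (lmFit, then eBayes with an intensity trend) with a mean per group, 3 residual degrees of freedom and 6.94 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested probe sets, with a threshold of 0.05. Fold changes are on the log2(value + 16) scale, which understates the change of dim probe sets. Means and standard deviations (SD) are of the deposited intensities, while standard errors (SE) are of the log2 difference. An SE given for a median over several genes comes from the spread among those genes, which are not independent replicates. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.

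The 3 comparisons were elo-5 C13ISO minus elo-5 C17ISO, elo-5 C13ISO minus N2 C13ISO, and elo-5 C17ISO minus N2 C13ISO. N2 larvae given C17ISO were not analysed here, so the last comparison differs in both genotype and supplement. In addition, 35 gene lists covering lipid metabolism, other metabolism, structural genes, stress and signalling genes and markers of cell types were tested with limma's camera at a preset correlation of 0.01. The camera test asks whether a list's members shift against all other genes, and its p-values were adjusted over the lists of a comparison. It was repeated with a correlation estimated per list, a version that also tests with the 3 residual degrees of freedom. A call lost there therefore need not reflect correlated members where the estimate is near or below the preset. For the glycolysis list in elo-5 C13ISO minus elo-5 C17ISO, the estimate was 0.0051, below the preset 0.01. Its camera p, not adjusted, nonetheless rose from 1.9e-05 to 0.021. Limma's fry was run as a test of each list on its own. A list needed 5 measured members to be tested. Counts of changed members are also given adjusted over the list alone.

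The named genes were the 10 largest increases and 10 largest decreases in each comparison with elo-5 C13ISO, and 5 of each in the remaining comparison. They had to be past the threshold, carry 1 gene name and have arrays of the 2 groups that did not overlap. Up to 4 members of each list with the largest called differences were also eligible, along with elo-5 and elo-6. The groups, the test, the filter, the lists, the rule for named genes and the alternatives were fixed before the data were examined.

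Alternatives were an offset of 1 or 64, no filter or a filter at the 50th percentile, quantile normalization, alignment of array medians, eBayes without a trend or with a robust prior, and a fit of only the arrays compared. A replicate block, a threshold of 2-fold, the mean of all probe sets of a gene for the lists, and leaving out each array in turn were also tried. The fit was tested on simulated data with 15783 probe sets, 200 of them changed, in 20 simulations. For elo-5 C13ISO minus elo-5 C17ISO it recovered 65.7% of 2-fold and 99.2% of 4-fold changes, with 4.47% false calls. For elo-5 C13ISO minus N2 the values were 67.2%, 99.1% and 4.92%, and with no simulated change elo-5 C17ISO minus N2 gave 0 calls. A list shifted by -0.50 log2 was found by camera in 20 of 20 simulations with the preset correlation and in 15 with an estimated one, with 0.15 other lists called per simulation. The simulated probe sets varied independently, while the correlation estimated for the oocyte and early embryo markers was 0.588. These list rates therefore do not carry over to correlated lists, and the simulations changed far fewer probe sets than the data. Because 2 comparisons share the elo-5 C13ISO arrays, unchanged groups sharing 1 group were simulated 100 times to measure the overlap that sharing gives when no probe set changes. Groups of 2 arrays are too small for tests of outlying arrays or of other divisions of the arrays.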

Results

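The data comprised 6 arrays of unfed L1 larvae, 2 for each of elo-5 C13ISO, elo-5 C17ISO and N2 C13ISO. C13ISO and C17ISO are saturated fatty acids with a methyl branch near the end of the chain, and C17ISO has the longer chain. The gene elo-5 encodes a fatty acid elongase needed to make C17ISO, so mutants depend on a supplement. Spearman correlations were 0.984 to 0.989 between the arrays of a group. Arrays of elo-5 C13ISO correlated at 0.926 to 0.943 with those of the other groups, whereas elo-5 C17ISO and N2 arrays correlated at 0.981 to 0.982. The first principal component held 81.9% of the variance and set the 2 elo-5 C13ISO arrays apart from the other 4. The next held 8.28% and set the elo-5 C17ISO arrays (-19.5 and -20.2) apart from the N2 arrays (21.6 and 17.7).

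The elo-5 probe set read 181 ± 51.7 (SD, n = 2) in elo-5 C13ISO, 162 ± 22.7 in elo-5 C17ISO and 1389 ± 310 in N2. It was 7.18-fold lower in elo-5 C13ISO than in N2 (log2 -2.84, SE 0.22, adjusted p = 5.3e-06) and 7.82-fold lower in elo-5 C17ISO (adjusted p = 2.1e-04). Between the mutant groups the log2 difference was 0.12, with a 95% interval of -0.38 to 0.62 and adjusted p = 0.689. Where this probe set lies relative to the gk208 deletion is not given in the sources used here, and one outside the deleted part would not check the labels. The related elongase gene elo-6, which acts in the same synthesis, read 1010 ± 1.15 in elo-5 C13ISO, 2008 ± 424 in elo-5 C17ISO and 2185 ± 110 in N2. Its fall in elo-5 C13ISO was 1.95-fold against elo-5 C17ISO (adjusted p = 4.4e-04) and 2.14-fold against N2 (adjusted p = 1.7e-04). The log2 difference of elo-6 between elo-5 C17ISO and N2 was -0.14, with an interval of -0.46 to 0.19.

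**Figure D1:**
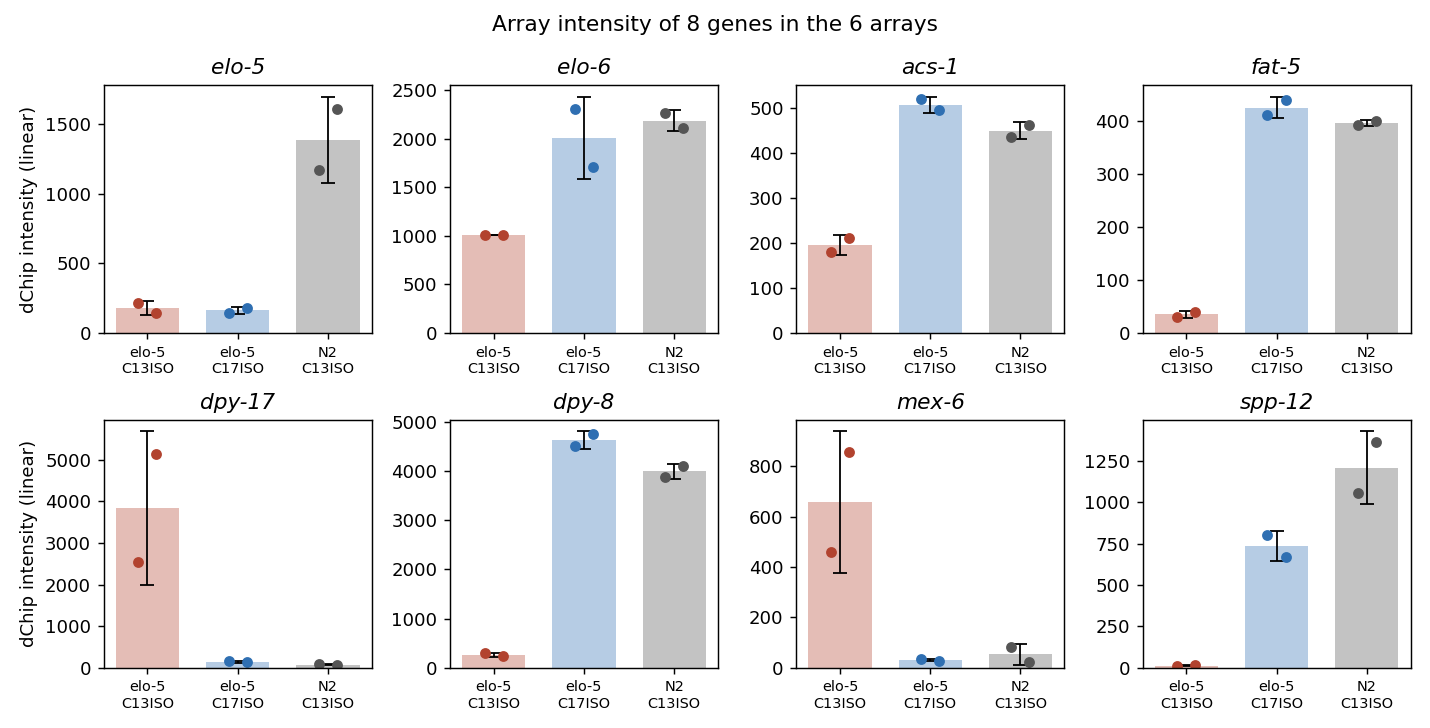
Deposited intensities (linear scale, dChip expression level) of 8 genes in the 3 groups; bars are means of 2 arrays, error bars SD and points single arrays, 6 per gene. The elo-5 bar is low in both mutant groups (181 and 162 against 1389 in N2), while dpy-17 (3836) and mex-6 (657) are high and spp-12 (13) is low in elo-5 C13ISO.

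The comparison of elo-5 C13ISO with elo-5 C17ISO asked how larvae of 1 genotype differed when their mothers had received related fatty acids at a matched 1 mM. In elo-5 C13ISO 13 of 20 genes of fatty acid elongation and desaturation, 20 of 32 genes of beta-oxidation and 58 of 101 cuticle collagens fell, and 21 of 23 oocyte and early embryo markers rose. These lists passed camera with the preset correlation and not with an estimated one (adjusted p = 0.353 for each of the lists that fell and 0.497 for the oocyte and early embryo markers). The fatty acid desaturase gene fat-5 fell 8.67-fold, the carnitine palmitoyltransferase gene cpt-5 fell 8.55-fold, and the cuticle collagen gene dpy-8 fell 16.7-fold, from 4622 ± 178 to 263 ± 43.4 (SD, n = 2, log2 SE 0.13). The collagen gene dpy-17 rose 22.8-fold, from 144 ± 21.4 to 3836 ± 1844 (SE 0.28). Of 15783 probe sets, 7026 changed (44.5%), 4062 higher and 2964 lower in elo-5 C13ISO, or 3488 genes higher and 2514 lower, with 26 genes among both. The percentage higher among the changed was 57.8% as deposited, 51.6% after quantile normalization and 36.2% with array medians aligned, while the median log2 difference of all probe sets moved from 0.07 to -0.01 and -0.16. In the limma test 2903 changed by at least 2-fold. The arrays of the 2 groups did not overlap at 71.4% of all probe sets, against 33.3% expected by chance.

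The largest increases were in Y47H10A.5, which rose 26.4-fold (2986 ± 252 against 97.7 ± 10.8, adjusted p = 2.4e-07), and Y37H2A.14, which rose 25.2-fold (3416 ± 196 against 120 ± 7.89, adjusted p = 5.8e-08). The claudin-like gene clc-12 rose 20.2-fold, the Rab GTPase gene rab-11.2 rose 20.1-fold, B0024.4 rose 19.2-fold, and the collagen genes dpy-14 and col-165 rose 22.1-fold and 13.5-fold. The saposin-like gene spp-27 rose 15.7-fold, a log2 difference of 3.97 that became 2.62 with an offset of 64. The CCCH zinc finger gene mex-6, which acts in early embryo polarity, rose 13.6-fold (SE 0.40). The largest decrease was in the saposin-like gene spp-12, which read 13 ± 2.2 against 735 ± 92.8 and fell 26.2-fold (adjusted p = 9.1e-08). ZK180.6 fell 19.2-fold, T06G6.6 18.2-fold, and bah-1, required for bacterial biofilms to stick to the head, 17.7-fold. The collagen genes dpy-9 and col-128 fell 17.7-fold and 15.3-fold, K02E2.8 15.1-fold and Y46G5A.29 14.8-fold. F07E5.7 fell by 4.09 on the log2 scale. The elo-5 C13ISO means of spp-12, F07E5.7 and Y46G5A.29 lay below the offset of 16, so the size and the rank of their falls depend on it. With an offset of 64 their log2 differences were -3.38, -2.71 and -2.61.

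Of 20 measured genes of fatty acid elongation and desaturation, 13 fell, 0 rose and 7 were not called, with 13 lower when adjusted over the list alone. Alongside fat-5, the elongase gene elo-4 fell 6.29-fold and acs-1, an acyl-CoA synthetase acting on branched fatty acids, fell 2.49-fold. The list's median log2 difference was -0.67 (camera adjusted p = 5.9e-05; adjusted p = 0.353 with an estimated correlation). Of 32 beta-oxidation genes 20 fell and 2 rose (20 and 3 adjusted over the list alone), with a median of -0.89 (adjusted p = 2.8e-07; 0.353 with an estimated correlation). The acyl-CoA dehydrogenase gene acdh-6 fell 7.12-fold, and the enoyl-CoA hydratase genes ech-4 and ech-1.1 fell 6.02-fold and 5.49-fold. Acyl-CoA synthetases fell in 11 of 19 cases and rose in 3, or 12 and 3 adjusted over the list alone (median -0.62, adjusted p = 0.00218; 0.353 with an estimated correlation), including acs-2 (3.42-fold), acs-20 (2.80-fold) and acs-14 (2.45-fold). The branched-chain amino acid and propionate catabolism list held 19 genes, of which 11 fell and 2 rose, or 11 and 3 adjusted over the list alone. It had a median of -0.50 (adjusted p = 0.00354; 0.354 with an estimated correlation), and hach-1 (3.63-fold), hphd-1 (2.63-fold) and ech-6 (2.48-fold) fell. The list of lipases, lipid binding and lipid storage had 12 of 22 lower and 3 higher, the same adjusted over the list alone, for example lipl-5 at 2.04-fold lower (median -0.52, adjusted p = 0.0111; 0.353 with an estimated correlation; 0.073 with a filter at the 50th percentile). In the same arrays 21 of 23 oocyte and early embryo markers rose.

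Among 101 cuticle collagens, 58 fell, 10 rose and 33 were not called, or 60 and 10 adjusted over the list alone. The median was -0.56 (adjusted p = 1.8e-11; 0.353 with an estimated correlation; fry adjusted p = 0.00316). In glycolysis, gluconeogenesis and glyoxylate cycle 12 of 20 fell and 1 rose, the same adjusted over the list alone, with pyc-1 (2.76-fold), fbp-1 (2.72-fold) and pck-1 (2.25-fold) lower (median -0.35, adjusted p = 1.1e-04; 0.353 with an estimated correlation). In oxidative phosphorylation 14 of 44 fell and 4 rose, or 14 and 3 adjusted over the list alone. The median was -0.13 (adjusted p = 0.026; 0.354 with an estimated correlation), the respiratory complex genes ucr-2.2 and gas-1 had log2 differences of -0.71 and -0.62, and sdha-2 rose 2.63-fold. That call was lost with a filter at the 50th percentile (0.0717), under quantile normalization (0.137), without an intensity trend (0.0645) and without elo-5 C13ISO replicate 1 (0.0583).

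Of 23 oocyte and early embryo markers, 21 rose and 0 fell (23 rose adjusted over the list alone), with a median 4.67-fold rise (log2 2.22, adjusted p = 6.7e-09; 0.497 with an estimated correlation; fry adjusted p = 0.0158). Beside mex-6, the oocyte maturation gene oma-2 rose 12.3-fold, the eggshell gene cpg-2 rose 10.3-fold and mex-5 rose 9.90-fold. Germ granule and meiosis markers rose in 16 of 20 cases and fell in 0, or 17 and 0 adjusted over the list alone (median 1.09, adjusted p = 1.0e-04; 0.497 with an estimated correlation). Examples were gld-1 (8.98-fold), the Argonaute gene wago-1 (4.66-fold) and the synaptonemal complex gene syp-2 (3.87-fold). Of 32 genes switched on in early embryos, 12 rose, 2 fell and 18 were not called. All were tested with no filter because the filter keeps dim genes that rose, and their median was 0.44 (SE over genes 0.244). Among them vet-6 (log2 2.35), vet-2 (1.85) and pes-10 (1.89) rose, and sdz-24 (-2.22) and sdz-6 (-0.50) fell. Sperm markers fell in 4 of 14 cases and rose in 0, the same adjusted over the list alone (median -0.35, adjusted p = 0.0879). The sperm protein gene msp-65 fell 1.61-fold, a call lost without elo-5 C17ISO replicate 1 (adjusted p = 0.055). Of 5 vitellogenins on the array, 2 passed the filter, vit-6 and vit-4, and they differed by -0.12 (interval -0.54 to 0.30) and 0.12 (-0.39 to 0.63). With no filter the dim vit-1 was higher (34 against 12, adjusted p = 0.00952), and vit-2 and vit-5 were not called. Of 13 embryonic morphogenesis and hatching-stage transcription factors 2 rose and 2 fell, the same adjusted over the list alone, with cnd-1 5.65-fold lower and pha-4 1.8-fold higher (median -0.15, adjusted p = 0.687).

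Glutathione S-transferases rose in 24 of 44 cases and fell in 7, or 24 and 8 adjusted over the list alone (median 0.70, adjusted p = 0.0111; 0.711 with an estimated correlation), with gst-38 9.28-fold higher and gsto-1 6.30-fold lower. Of 182 nuclear hormone receptors 69 rose and 20 fell, the same adjusted over the list alone (median 0.34, adjusted p = 0.0161; 0.711 with an estimated correlation). Among them nhr-210 rose 4.79-fold and nhr-265 fell 11.9-fold, and the list's call was lost without elo-5 C13ISO replicate 1 (0.0673). The list of 74 cytosolic ribosomal proteins had 8 higher and 0 lower, none of them adjusted over the list alone (median 0.12, adjusted p = 0.0141; 0.825 with an estimated correlation). The sign of its median depends on the scaling, since aligning array medians lowers every probe set by the same amount, taking the median of all from 0.07 to -0.16, and turned the list too. Such a shift leaves the list's place relative to the other genes, which camera tests, unchanged. The call was lost without elo-5 C13ISO replicate 1 (0.132) and without an intensity trend (0.342). The members rpl-22 and rpl-27 had log2 differences of 0.22 and 0.21.

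The other lists did not pass camera in this comparison, with medians in log2 and counts adjusted over the list alone in parentheses. Sphingolipid metabolism had 11 of 19 higher and 2 lower (11 and 3; median 0.51, adjusted p = 0.0529), with the ceramide gene hyl-1 3.03-fold and the glucosyltransferase gene cgt-1 3.15-fold higher, and passed under quantile normalization (0.0312). DAF-16 activated genes had 5 of 18 higher and 9 lower (5 and 9; -0.24, adjusted p = 0.0529), with dod-3 4.08-fold and lys-7 3.96-fold lower. DAF-16 repressed (dod) genes had 5 of 12 higher and 3 lower (5 and 4; 0.27, adjusted p = 0.868), with dod-19 13-fold higher. Of 26 genes of TORC1, TORC2 and nutrient sensing 8 rose and 0 fell (8 and 0; 0.24, adjusted p = 0.109), with daf-18 2.97-fold higher. Insulin-like peptides had 7 of 21 higher and 5 lower (8 and 5; 0.11, adjusted p = 0.793), with ins-30 2.65-fold higher. Neuropeptides had 18 of 50 higher and 12 lower (19 and 13), with nlp-6 3.16-fold higher, a median of -0.02, a mean of 0.21 and a camera direction of down (adjusted p = 0.945). Synaptic and pan-neuronal genes had 5 of 26 higher and 0 lower (3 and 0; 0.08, adjusted p = 0.69), and unc-18 rose 1.57-fold. Body wall and pharyngeal muscle had 10 of 30 higher and 3 lower (10 and 3; 0.18, adjusted p = 0.0879), with the myosin gene myo-5 3.38-fold higher, and passed under quantile normalization (0.0153).

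Of 60 genes of autophagy and lysosome 16 rose and 15 fell (17 and 16 adjusted over the list alone; median -0.02, adjusted p = 0.541), with the protease genes asp-8 and asp-14 5.63-fold and 5.59-fold lower. The endoplasmic reticulum unfolded protein response had 3 of 23 higher and 4 lower (3 and 4; -0.02, adjusted p = 0.69), with ire-1 1.88-fold higher. The mitochondrial unfolded protein response had 6 of 17 higher and 3 lower (6 and 3; 0.21, adjusted p = 0.69), with hsp-6 1.67-fold higher and hsp-60 1.57-fold lower. Cytosolic heat shock proteins had 7 of 19 higher and 2 lower (7 and 2; 0.12, adjusted p = 0.148), with sip-1 9.43-fold and hsp-17 4.57-fold higher. UDP-glucuronosyltransferases had 23 of 55 higher and 9 lower (25 and 12; 0.41, adjusted p = 0.34), and cytochrome P450 enzymes had 23 of 60 higher and 14 lower (24 and 16; 0.17, adjusted p = 0.923), with ugt-9 4.89-fold higher and cyp-13B1 9.56-fold lower. Lysozymes, C-type lectins and antimicrobial peptides had 41 of 140 higher and 45 lower (41 and 45; median -0.07, mean 0.00, adjusted p = 0.384), with spp-13 9.51-fold lower. Trehalose and glycogen metabolism had 2 of 14 higher and 4 lower (2 and 4; -0.25, adjusted p = 0.0845), with aagr-4 6.36-fold lower. Intestine markers had 9 of 22 higher and 6 lower (9 and 8; median 0.07, mean 0.12, camera direction down, adjusted p = 0.945), with the protease genes cpr-3 4.34-fold higher and cpr-5 4.57-fold lower. Cell cycle and DNA replication had 9 of 36 higher and 7 lower (9 and 7; median 0.03, mean 0.13, camera direction down, adjusted p = 0.807), with the cyclin gene cyb-2.2 7.73-fold higher. Chemosensory receptor families had 22 of 211 higher and 24 lower (20 and 16; -0.12, adjusted p = 0.0961), with odr-10 4.29-fold higher.

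**Figure D2:**
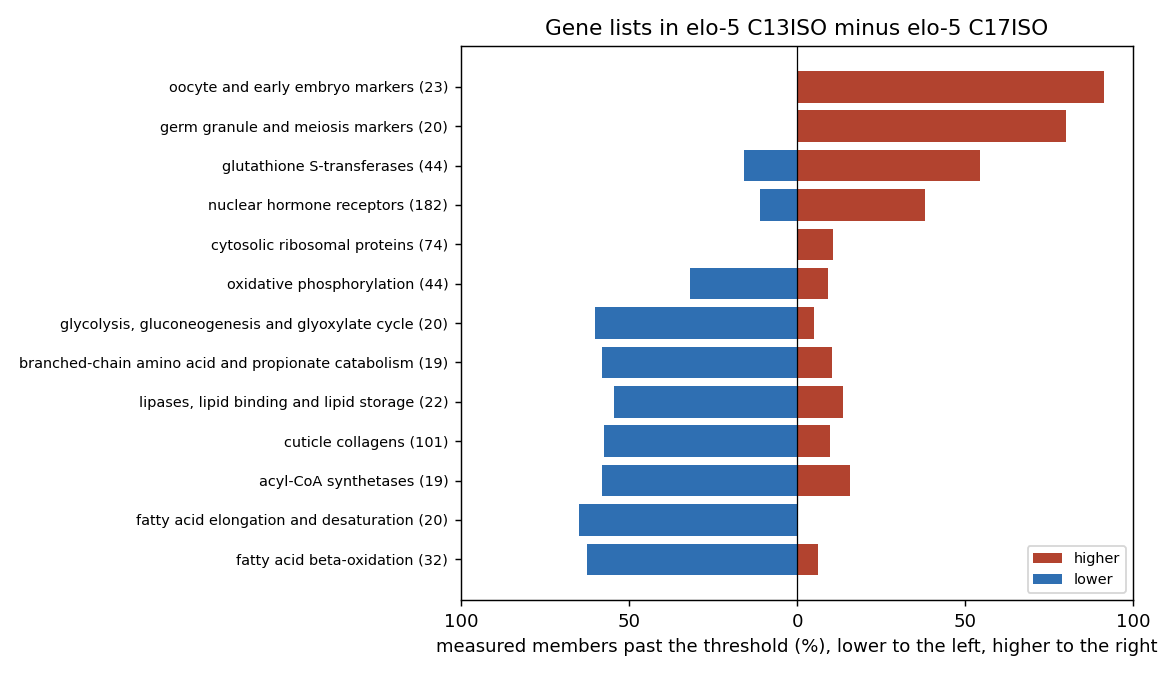
Percentage of the measured members of each list that were higher or lower in elo-5 C13ISO than in elo-5 C17ISO, for the 13 lists past camera with the preset correlation. Oocyte and early embryo markers have 21 of 23 higher and cuticle collagens 58 of 101 lower. Ribosomal proteins have 8 of 74 higher, and the sign of their median depends on the scaling of the arrays.

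The comparison of elo-5 C13ISO with N2 C13ISO held the supplement constant and changed the genotype. In the mutants 14 of 20 genes of fatty acid elongation and desaturation, 21 of 32 genes of beta-oxidation and 66 of 101 cuticle collagens fell, and 22 of 23 oocyte and early embryo markers rose. With an estimated correlation none of these list calls held (adjusted p = 0.287, 0.378, 0.262 and 0.518 in that order). The collagen genes dpy-14 (1713 ± 667 against 24 ± 6.3) and dpy-17 rose 41.9-fold and 39.6-fold (n = 2, SE 0.28 each), and the receptor gene srv-7 fell 43-fold, from 4356 ± 118 to 85.7 ± 4.65 (adjusted p = 3.4e-08). Of 15783 probe sets, 6875 changed (43.6%), 3655 higher and 3220 lower in the mutants, or 3119 genes higher and 2699 lower, with 14 genes among both. The percentage higher among the changed was 53.2% as deposited, 50.8% after quantile normalization and 38.4% with array medians aligned. In the limma test 2943 changed by at least 2-fold. Without N2 C13ISO replicate 2 the number changed was 4582, the lowest of the fits with an array left out.

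Further increases were in Y37H2A.14 (35.5-fold), Y47H10A.5 (29.6-fold), clc-12 (22.8-fold), rab-11.2 (18.7-fold), B0024.4 (18.3-fold), F22E5.6 (16-fold) and Y41D4B.17 (15.9-fold). The saposin-like gene spp-27 rose 19.9-fold, a log2 difference of 4.32 that became 2.74 with an offset of 64. Among decreases, spp-12 fell 42.5-fold, ZK180.6 23.3-fold, bah-1 22.6-fold, C04F1.1 18.2-fold and T06G6.6 16.3-fold. The hedgehog-related gene wrt-4 fell 15.4-fold, oac-24 15.1-fold, the infection response gene irg-5 14.9-fold and dpy-8 14.4-fold. Means of spp-12 and oac-24 in elo-5 C13ISO and of F22E5.6 and spp-27 in N2 lay below the offset of 16, and with an offset of 64 the log2 differences of spp-12, oac-24 and F22E5.6 were -4.04, -2.69 and 2.76.

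Fatty acid elongation and desaturation had 14 of 20 lower and 1 higher, or 16 and 1 adjusted over the list alone, among them fat-5 (8.10-fold), elo-4 (6.59-fold) and the desaturase gene fat-1 (2.32-fold). Its median was -0.87 (camera adjusted p = 2.4e-06; adjusted p = 0.287 with an estimated correlation). In beta-oxidation 21 of 32 fell and 4 rose, or 22 and 4 adjusted over the list alone (median -0.68, adjusted p = 9.7e-05; 0.378 with an estimated correlation), including acdh-6 (7.96-fold), cpt-5 (6.98-fold) and ech-4 (5.87-fold). Acyl-CoA synthetases had 9 of 19 lower and 2 higher, or 11 and 3 adjusted over the list alone (-0.42, adjusted p = 0.0147; 0.378 with an estimated correlation), with acs-20 3.44-fold lower. The branched-chain amino acid and propionate catabolism list had 12 of 19 lower and 3 higher, or 13 and 3 adjusted over the list alone, with hach-1 3.73-fold and the epimerase gene mce-1 2.37-fold lower (-0.67, adjusted p = 0.00132; 0.378 with an estimated correlation). The list of lipases, lipid binding and lipid storage had 13 of 22 lower and 3 higher, the same adjusted over the list alone, with lipl-1 3.0-fold lower (-0.58, adjusted p = 0.0173; 0.378 with an estimated correlation; 0.211 with a filter at the 50th percentile). The list of sphingolipid metabolism had 11 of 19 higher and 3 lower, the same adjusted over the list alone, with lagr-1 6.37-fold and asah-2 3.43-fold higher (0.67, adjusted p = 0.0495; 0.378 with an estimated correlation). That call was lost without elo-5 C13ISO replicate 1 (0.0509), without N2 C13ISO replicate 1 (0.072), with an offset of 64 (0.0548), with no filter (0.0561), without an intensity trend (0.0683) and with a replicate block (0.0588). In these arrays oocyte and early embryo markers rose in 22 of 23 cases.

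Cuticle collagens had 66 of 101 lower and 12 higher, or 69 and 14 adjusted over the list alone (median -0.68, adjusted p = 1.2e-12; 0.262 with an estimated correlation). Oxidative phosphorylation had 23 of 44 lower and 2 higher, or 26 and 2 adjusted over the list alone, with ucr-2.2 1.74-fold lower (-0.25, adjusted p = 1.9e-04; 0.262 with an estimated correlation). In glycolysis, gluconeogenesis and glyoxylate cycle 13 of 20 fell and 1 rose, the same adjusted over the list alone, with fbp-1 3.20-fold lower and the hexokinase gene hxk-1 2.55-fold higher (-0.48, adjusted p = 8.8e-05; 0.262 with an estimated correlation). DAF-16 activated genes had 10 of 18 lower and 4 higher, or 10 and 5 adjusted over the list alone, with dod-3 5.06-fold and dao-3 3.50-fold lower (-0.53, adjusted p = 0.0173; 0.546 with an estimated correlation). Oocyte and early embryo markers had 22 of 23 higher and 0 lower, the same adjusted over the list alone, with oma-2 12.7-fold and oma-1 6.92-fold higher (median 1.98, adjusted p = 2.4e-08; 0.518 with an estimated correlation). Germ granule and meiosis markers had 13 of 20 higher and 0 lower, or 14 and 0 adjusted over the list alone, with gld-1 4.66-fold higher (1.25, adjusted p = 1.9e-04; 0.518 with an estimated correlation). Glutathione S-transferases had 25 of 44 higher and 8 lower, or 26 and 8 adjusted over the list alone, with gst-24 3.75-fold higher (0.66, adjusted p = 0.0147; 0.635 with an estimated correlation). Nuclear hormone receptors had 76 of 182 higher and 19 lower, or 80 and 19 adjusted over the list alone, with nhr-178 5.62-fold higher and nhr-114 7.12-fold lower (0.33, adjusted p = 0.00132; 0.518 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 74 called by limma (median -0.02, adjusted p = 0.523).

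Set against both references, elo-5 C13ISO shared 5639 changed probe sets in the same direction, 3111 higher and 2528 lower, which was 80.3% of those changed against elo-5 C17ISO. Y47H10A.5, Y37H2A.14, dpy-17, dpy-14 and clc-12 led the shared increases, and spp-12, ZK180.6, bah-1, T06G6.6 and dpy-8 led the shared decreases. Simulated unchanged groups sharing the elo-5 C13ISO arrays gave 0.06 shared probe sets on average and 2 at most, a number bound to be small because such groups yield almost no calls. Independent lists of these sizes would share 1545. The log2 differences correlated at r = 0.937 across probe sets, which are not independent replicates, against 0.497 simulated. Their covariance was 0.757 against 0.0175 simulated, a difference of 0.74. The elo-5 C13ISO arrays could not be divided with 2 in each part, so part of the excess may come from the shared arrays. Of the shared probe sets, 5541 were not called between elo-5 C17ISO and N2 and 98 were. In 17 probe sets the calls went in opposite directions, including those of dbd-18, srv-7, spp-8 and col-39.

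**Figure D3:**
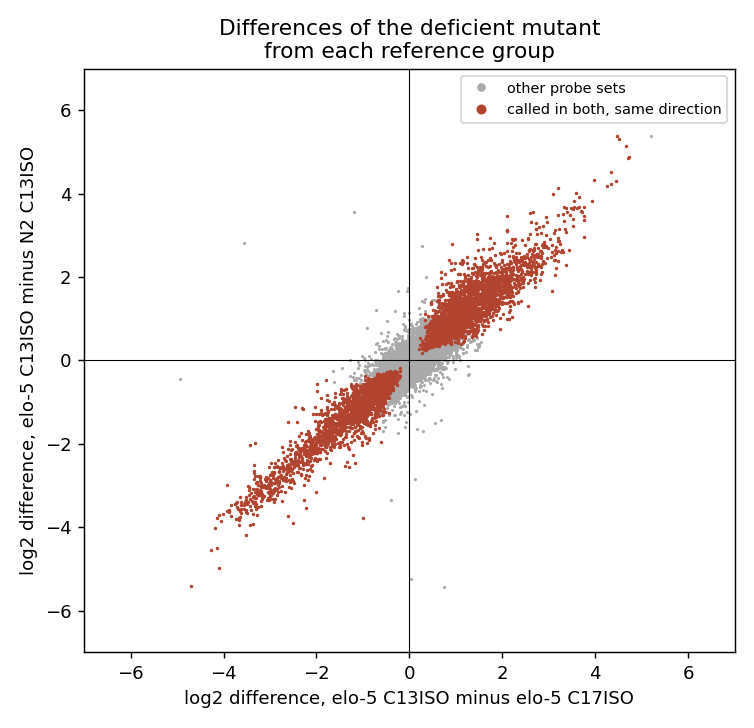
Log2 difference of elo-5 C13ISO against elo-5 C17ISO (x axis) and against N2 C13ISO (y axis) for the tested probe sets, 1 point each, red where called in the same direction in both. The points follow a common line (r = 0.937), with 5639 in red and srv-7 far below it.

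The comparison of elo-5 C17ISO with N2 C13ISO asked how far the mutants given C17ISO lay from wild type, and it differed in both genotype and supplement. Far fewer probe sets passed, and the largest differences were in single genes. Expression of dbd-18 was 82.9-fold higher in the mutants (1734 ± 125 against 5.09 ± 0.375, SD, n = 2, SE 0.17, adjusted p = 3.4e-08), and srv-7 was 71.6-fold lower (45.1 ± 2.43 against 4356 ± 118, SE 0.15). The N2 values of dbd-18 lay below the offset of 16, which lowers its fold, and its log2 difference of 6.37 became 4.70 with an offset of 64. Of 15783 probe sets, 222 changed (1.41%), 121 higher and 101 lower, and 99 of them by at least 2-fold, while 2474 had an unadjusted p under 0.05. The arrays of these 2 groups did not overlap at 50.9% of all probe sets, against 33.3% expected by chance. The percentage higher among the changed was 54.5% as deposited, 62.9% after quantile normalization and 69.6% with array medians aligned. The count was 26 without elo-5 C17ISO replicate 1, 38 without its replicate 2, 48 without N2 C13ISO replicate 1 and 29 without its replicate 2. It was 504 without either elo-5 C13ISO array.

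Of these probe sets 141 were also called in the same direction in elo-5 C13ISO minus N2. With each gene read from its brightest probe set alone, 113 genes were so called. Of the 141, 54 were not called between the elo-5 groups and 87 were, for example dbd-18, which was lower in elo-5 C13ISO than in elo-5 C17ISO (log2 -3.57). Simulated unchanged groups sharing the N2 arrays gave 2 at most, but without changed probe sets they yield almost no calls to share. Independent lists would share 48.6. The log2 differences correlated at r = 0.201 across probe sets, below the 0.501 simulated, and their covariance was 0.0578 against 0.0177 simulated, a difference of 0.0401. The N2 arrays could not be divided with 2 in each part, so part of the 141 may come from the shared arrays.

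The scaffold gene cnk-1 rose 5.57-fold (308 ± 42.5 against 42.2 ± 7.92, adjusted p = 2.1e-04) and Y73B3B.5 rose 3.76-fold (adjusted p = 8.3e-04). The astacin protease gene nas-6 rose 3.67-fold (738 ± 180 against 190 ± 50.7), a call lost without elo-5 C17ISO replicate 2 (adjusted p = 0.0668). The receptor gene srw-17 rose 3.77-fold, a call lost without elo-5 C17ISO replicate 1 (0.0591) and without N2 C13ISO replicate 2 (0.0735), and its log2 difference of 1.91 became 1.23 with an offset of 64. Besides elo-5, the cadherin gene cdh-10 fell 7.72-fold (adjusted p = 1.9e-04), the C-type lectin gene clec-52 fell 6.94-fold and gcsh-1, of the glycine cleavage system, fell 4.36-fold. With an offset of 64 the log2 difference of cdh-10 went from -2.95 to -1.92 and that of gcsh-1 from -2.12 to -1.32.

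Beta-oxidation had 4 of 32 genes higher, 0 lower and 28 not called, or 6 higher and 0 lower adjusted over the list alone (median 0.17, camera adjusted p = 9.2e-06; adjusted p = 0.634 with an estimated correlation). The 4 were ech-1.1 (2.55-fold, adjusted p = 0.00879), cpt-3 (log2 0.96), pmp-1 (1.82-fold) and cpt-4 (1.81-fold), and each call was lost without any 1 of the 4 arrays compared, for example ech-1.1 without elo-5 C17ISO replicate 1 (0.107) or replicate 2 (0.0891) and without N2 C13ISO replicate 1 (0.0584) or replicate 2 (0.133). Neuropeptides passed camera as higher with 0 of 50 called and 9 higher adjusted over the list alone (median 0.21, adjusted p = 1.1e-08; 0.634 with an estimated correlation), and flp-14 had a log2 difference of 0.64 (adjusted p = 0.0978). Cytosolic ribosomal proteins passed as lower with 0 of 74 called and 0 adjusted over the list alone (median -0.13, camera adjusted p = 1.0e-10). Their camera adjusted p was 0.634 with an estimated correlation, and the call was lost under quantile normalization (0.361). That correlation was 0.432, and it was 0.247 for the neuropeptides, both far above the preset 0.01. Oxidative phosphorylation passed as lower with 0 of 44 called and 2 lower adjusted over the list alone (-0.11, adjusted p = 0.00102; 0.634 with an estimated correlation), and asb-2 had a log2 difference of -0.40 (adjusted p = 0.0648). On fry, which tests a list without setting it against other genes, 0 of 34 lists passed in this comparison (adjusted p = 0.261 for beta-oxidation) and 5 had an unadjusted p under 0.05. It passed 19 and 21 lists in the comparisons with elo-5 C13ISO, and the difference was not tested. The mixed fry test, which asks whether members change in either direction, passed 20 lists here (adjusted p = 0.00362 for beta-oxidation) and 34 and 33 in the other comparisons.

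The chemosensory receptor families had 6 of 211 higher and 1 lower, or 11 and 2 adjusted over the list alone (median 0.09, adjusted p = 0.00135; 0.634 with an estimated correlation), with sri-31 2.74-fold higher. That list's call was lost without N2 C13ISO replicate 1 (0.0512), with no filter (0.0699) and with a filter at the 50th percentile (0.275), and that of sri-31 without elo-5 C17ISO replicate 1 (0.0591). Nuclear hormone receptors had 2 of 182 higher and 2 lower, or 4 and 2 adjusted over the list alone (0.06, adjusted p = 0.0176; 0.697 with an estimated correlation). Of these, nhr-158 was 2.84-fold higher, a call lost without elo-5 C17ISO replicate 1 (0.0591), and the list's call was lost without elo-5 C17ISO replicate 2 (0.07), without N2 C13ISO replicate 2 (0.0632) and with no filter (0.09). Cytochrome P450 enzymes had 2 of 60 higher and 2 lower, or 4 and 3 adjusted over the list alone (0.11, adjusted p = 0.0265; 0.634 with an estimated correlation), a call lost without elo-5 C17ISO replicate 2 (0.103), without N2 C13ISO replicate 2 (0.159) and with no filter (0.182). Insulin-like peptides had 0 of 21 called and 1 lower adjusted over the list alone (0.26, adjusted p = 0.0265; 0.634 with an estimated correlation), with ins-4 at 0.64 (adjusted p = 0.172). That call was lost without elo-5 C17ISO replicate 1 (0.174), without N2 C13ISO replicate 1 (0.232), with no filter (0.116) and with a filter at the 50th percentile (0.058).

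The oocyte and early embryo markers had 0 of 23 called by limma between elo-5 C17ISO and N2 (median -0.26, adjusted p = 0.114). That list passed, as lower in elo-5 C17ISO, without elo-5 C17ISO replicate 1 (0.0183), without N2 C13ISO replicate 2 (0.00929) and with array medians aligned (0.0493). Cuticle collagens had 4 of 101 lower and 0 higher, or 8 and 3 adjusted over the list alone (median -0.05, mean 0.02, adjusted p = 0.784). The list of fatty acid elongation and desaturation had elo-5 as its 1 called gene of 20 (adjusted p = 0.0717). It passed, as lower, without elo-5 C17ISO replicate 1 (0.0183), without N2 C13ISO replicate 1 (0.0434) and with the mean of all probe sets of a gene (0.0418).

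**Figure D4:**
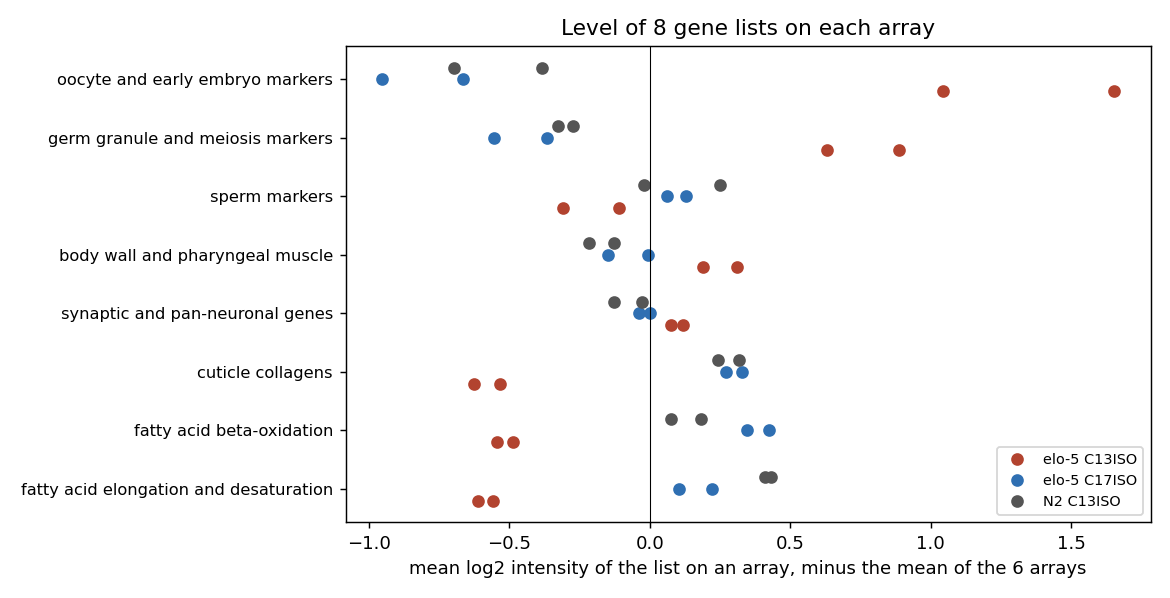
Mean log2 value of 8 gene lists on each of the 6 arrays, relative to the mean of the 6 arrays, with 1 point per array and the 3 groups in different colours. Oocyte and early embryo markers lie at 1.04 and 1.65 on the elo-5 C13ISO arrays and below 0 on the other 4, and cuticle collagens at -0.62 and -0.53 against values above 0.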

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

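Of the 375 values of named genes and list members, 325 of them past the threshold, alternatives other than leaving out an array gave 3573 values that kept direction and side of the threshold, 66 that lost the threshold, 20 that gained it and 4 that reversed. The 4 reversals were in elo-5 C13ISO minus elo-5 C17ISO with array medians aligned, at log2 -0.0078 for rpl-22, -0.018 for rpl-27, -0.025 for rpl-23 and -0.038 for rps-25, where that alignment took the median of all probe sets to -0.16. Leaving out an array gave 2077 kept, 153 lost, 20 gained and 0 reversed; a group left with 1 array was assumed to vary like the others. Probe sets changed ranged from 5342 to 6762 in elo-5 C13ISO minus elo-5 C17ISO, 4582 to 6913 in elo-5 C13ISO minus N2 and 26 to 504 in elo-5 C17ISO minus N2, and the shared number from 4114 to 5631. In elo-5 C17ISO minus N2 the count was 26 and 38 without elo-5 C17ISO replicate 1 or 2, 48 and 29 without N2 C13ISO replicate 1 or 2, and 504 without either elo-5 C13ISO array. Lists past camera ranged over 10 to 16, 13 to 16 and 6 to 9.

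The count in elo-5 C17ISO minus N2 was 222 as reported, 103 with no filter, which tested 22548 probe sets, and 84 without an intensity trend. It was 534 with only the arrays compared, which kept all 222. The log2 difference between replicates varied most in elo-5 C13ISO (SD 0.354, against 0.283 in elo-5 C17ISO and 0.230 in N2). That group enters the shared estimate of spread in the reported fit but not the log2 differences of this comparison. With the same 15783 probe sets tested, the 2 counts can differ only through the estimate of spread and its degrees of freedom. How much of this comes from the larger replicate differences of elo-5 C13ISO was not tested. A threshold of 2-fold, which can only remove calls, left 2903, 2943 and 99 in the 3 comparisons and 2407 shared. With no filter 4 lists passed camera in elo-5 C17ISO minus N2, and with an estimated correlation 0 passed in each comparison, with 4, 4 and 1 at an unadjusted p under 0.05. The estimated version has only 3 degrees of freedom, so for lists of low estimated correlation these losses need not come from correlation between members. Other lists past camera had high estimates. These were 0.588 for oocyte and early embryo markers, 0.432 for cytosolic ribosomal proteins, 0.275 for germ granule and meiosis markers and 0.247 for neuropeptides. There correlation may account for the loss as well. The robust prior and the 2-fold threshold were not run for the lists. Deviations of same-numbered arrays from their group means correlated at 0.0015 to 0.0818 across probe sets, so no marked common deviation by number was visible. The labels do not say whether same-numbered arrays were prepared together. A replicate block gave 7175, 6968 and 242 changed, 5705 shared and 13, 13 and 9 lists. With 2 arrays per group and 18.3% or more of the values per array below the offset of 16, differences among dim probe sets are the least certain.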

Other observations

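The gene families, the tests of adult material, of dilution, of scaling, of the early zygotic genes with no filter and of the sharing of N2 arrays, and the genes singled out here were chosen only after the results were seen. Families were formed by symbol prefix, keeping 102 with at least 10 measured genes after leaving out prefixes whose members were mostly in the fixed lists. They were tested with a one-sided Fisher exact test in each direction, adjusted over both. That test counts the genes of a family as independent, though they were read on the same arrays and may vary together. No version allowing for such correlation was run, so these p-values do not measure variation between arrays. All 14 measured bus genes, loci found by an altered response to a bacterium that adheres to the cuticle, fell in elo-5 C13ISO against elo-5 C17ISO (adjusted p = 1.5e-08), with bus-10 13-fold, bus-24 8.04-fold and bus-5 7.22-fold lower. Patched-related genes fell in 13 of 21 cases and rose in 2 (adjusted p = 6.3e-04), with ptr-15 7.49-fold lower, and ground-like genes in 10 of 17 with 4 rising (adjusted p = 0.00882), with grl-10 9.85-fold lower. The mec genes, most of them needed by touch receptor neurons, fell in 11 of 16 cases and rose in 1 (adjusted p = 6.3e-04), including mec-10 at 2.75-fold, mec-17 at 2.16-fold and the tubulin genes mec-12 at 2.1-fold and mec-7 at 1.90-fold. Short-chain dehydrogenases fell in 17 of 29 cases and rose in 8 (adjusted p = 1.6e-04), with dhs-6 7.93-fold lower. The dpy genes, several of them collagens already counted, fell in 15 of 24 cases and rose in 2 (adjusted p = 1.6e-04), and dbd genes fell in 8 of 13 and rose in 4 (0.019). Against N2 the bus (0 higher, 14 lower), ptr (2 and 14), dhs (6 and 18), dpy (2 and 15) and mec (1 and 9) families also passed.

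F-box genes of the fbxa family rose in 46 of 83 cases and fell in 10 against elo-5 C17ISO (Fisher exact test, adjusted p = 5.1e-06), with fbxa-53 5.79-fold and fbxa-215 5.2-fold higher. Skp1-related genes rose in 11 of 16 cases and fell in 1 (adjusted p = 0.016), with skr-5 8.73-fold and skr-9 8.45-fold higher. BTB and MATH domain genes rose in 11 of 18 cases and fell in 0 (adjusted p = 0.0442), with bath-46 3.3-fold higher, and claudin-like genes rose in 11 of 18 and fell in 6 (adjusted p = 0.0442), with clc-25 13.2-fold higher. These directions were kept under quantile normalization and with array medians aligned. Against N2 the fbxa (43 higher, 8 lower), skr (11 and 1) and bath (11 and 0) families also passed, as did the F-box family fbxc (14 and 1 of 26, adjusted p = 0.0348), which missed the threshold against elo-5 C17ISO (0.0523). Histone genes passed against elo-5 C17ISO (1 higher, 11 lower of 22, adjusted p = 0.0197) but not against N2 (0.108), as did the ground-like (0.059), claudin-like (0.231) and dbd (0.112) genes, and whether these differ between the comparisons was not tested. The antimicrobial peptide genes nlp-27, nlp-28, nlp-29, nlp-30 and nlp-31 were 1.57-fold to 1.90-fold higher in elo-5 C17ISO than in N2 (adjusted p = 0.012 for nlp-28 to 0.0499 for nlp-30). Their calls were lost without elo-5 C17ISO replicate 1 (0.115 to 0.223), without its replicate 2 (0.0529 to 0.193) and without N2 C13ISO replicate 2 (0.171 to 0.387), and all but nlp-27 without N2 C13ISO replicate 1 (0.0584 to 0.115). In elo-5 C13ISO against N2 the same genes were higher by log2 1.06 to 1.46. The probe set of gmeb-3 read 28838 on elo-5 C13ISO replicate 2 and 5.84 or less on the other 5 arrays, and that of K12H6.9 read 25031 on elo-5 C17ISO replicate 2 and 24.2 or less elsewhere. Whether these single-array values are signal or failures of the model fit was not tested.

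Oocyte and early embryo markers were higher in elo-5 C13ISO than in elo-5 C17ISO, with 21 of 23 called. Adult or gamete material carried over with the larvae was tested with sperm markers and vitellogenins, 14 and 2 of them above the filter. Their median log2 difference was -0.2712 (n = 16 genes, SE over genes 0.113) against 2.22 for the oocyte markers. Over all 42 on the array with no filter their median was -0.14 (SE over genes 0.0732). The sperm markers had an estimated correlation of 0.503, so an SE over genes does not measure variation between arrays. These values argue against carried-over sperm. They say less about adult worms, since of the vitellogenins only vit-6 and vit-4 passed the filter. Neither was called, and the dim vit-1 was higher (34 against 12, log2 0.83, adjusted p = 0.00952). The smaller of the oocyte list's medians under the 2 normalizations was 1.994. Aligning array medians lowers every probe set by the same amount, taking the median of all from 0.07 to -0.16. A step so small could not have removed a median of 2.22, so the values show only that neither scaling accounts for the rise. Unhatched early embryos collected with the larvae remain a candidate explanation that the values do not decide. The 17 early zygotic genes above the filter had a median of 1.649 (SE over genes 0.398). However, the filter keeps dim genes because they rose, and all 32 on the array had a median of 0.4352 (SE over genes 0.244). Of these, 12 were higher and 2 lower, and end-3, tbx-37 and tbx-38 were among those not called. Whether such embryos, or larvae that keep these transcripts, come from the C17ISO deficiency that defines this group was not tested, and both stay open.

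Cuticle collagens were lower in elo-5 C13ISO than in elo-5 C17ISO, with a median of -0.56 over 101 genes. The median was -0.7185 under the normalization that left it nearer 0. Aligning array medians lowers every probe set here, so it could only move this median away from 0. The values show only that neither scaling accounts for the fall. If material without muscle and neuron transcripts had diluted larval RNA, muscle and neuron genes would have fallen too. Their median was 0.133 (n = 56 genes, SE over genes 0.0778). Dilution by material that carries such transcripts, for example older embryos, is not covered by that test and stays open. A difference in the timing of cuticle synthesis in the deficient larvae is a candidate explanation that was not tested, and the rise of dpy-17 and dpy-14 beside the fall of dpy-8 and dpy-9 shows that the members did not move together.

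Against N2, 141 probe sets were called in the same direction in both elo-5 groups, 54 of them not called between the elo-5 groups and 87 called there too. With each gene read from its brightest probe set alone, 113 genes were so called. Independent lists would share 48.6 probe sets. The 100 simulations of unchanged groups sharing the N2 arrays gave 2 at most, but such groups yield almost no calls, so that number was bound to be small. The covariance of the log2 differences was 0.0578 against 0.0177 simulated, while their correlation (0.201) lay below the simulated 0.501. Part of the 141 may come from the shared arrays. It was 22 and 32 without elo-5 C17ISO replicate 1 or 2, 46 and 26 without N2 C13ISO replicate 1 or 2, and 303 and 273 without elo-5 C13ISO replicate 1 or 2, while cnk-1 (log2 2.75 and 2.48), cdh-10 (-3.34 and -2.95), srv-7, clec-52 and the metallothionein gene mtl-1 (-1.48 and -1.41) kept their calls in elo-5 C17ISO minus N2 without any 1 array. Variants acting on the genes beside elo-5 are argued against as the main cause. Of the other 112 genes, 0.8929% (1 gene) lay among the 200 measured genes nearest elo-5, where 1.86 would be found by chance (one-sided Fisher exact p = 0.848). That window cannot speak to a longer segment carried along with elo-5, or to a linked variant that acts on distant genes. Sequence differences under single probe sets are argued against for the 12 genes with another tested probe set, of which 75% (9) moved alike on it, as for srv-7 (38.1-fold and 38.9-fold lower than in N2). Linked variants outside that window or acting at a distance, variants elsewhere in the genome of the mutant strain, an effect of elo-5 itself and differences between stocks could each account for the rest. None of these was tested, and the 87 called between the elo-5 groups do not follow the genotype alone.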
